A study of Homo sapiens with 6 samples.

How the data were processed

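Oligo(dT)-selected RNA of MDA-MB-231 cells was sequenced in 6 libraries, 3 with tsRNA-Gly-5-0006 overexpressed and 3 controls. Per the labels, the submitters used cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d and edgeR with the build hg38; the annotation release and the strandedness of the libraries are not stated. The deposited table gives expected counts and FPKM for 25706 genes in each library. Deposited expected counts are whole numbers that are not scaled between libraries. The ratio of count to FPKM, compared between libraries, was constant over 345 single-transcript genes (coefficient of variation at most 0.0199%), and low values pile up at 1 and at multiples of 4. The counts were therefore taken to derive from StringTie's coverage estimate and not to be tallies of read pairs, so no counting intervals are given. The FPKM values were computed by the authors as fragments per kilobase of transcript, scaled to the mapped fragments of each library. Totals of the deposited counts were 54371226 to 74586916 per library. The low values at multiples of 4 leave open that about 4 deposited counts stand for 1 fragment. In that case these totals and the counts given below overstate the number of fragments 4 times. The limits of 10 and 40 counts used below would then stand for fewer fragments as well.

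Genes were tested with the edgeR 4.0.16 quasi-likelihood test in R 4.3.3, with TMM scaling, the filterByExpr filter with its minimum count of 10, and group as the only term. The test is 2-sided, and p-values were adjusted by the Benjamini-Hochberg method over the 15951 genes that passed the filter, with a threshold of 0.05. The common dispersion was 0.0943, a biological coefficient of variation of 30.7%. Standard errors and 95% confidence intervals come from this fit. Means and SDs are of the deposited FPKM values.

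Before the data were examined, the test, the 34 gene lists, the marker lists of other cells and the rule for named genes were fixed. Of 1067 list entries, 1032 were in the table. Lists were tested with camera of limma 3.58.1 at its preset correlation of 0.01, adjusted over the lists, beside camera with an estimated correlation and fry. Genes named are those that pass the test; because fewer than 10 did, also the 10 with the smallest unadjusted p that have a symbol and a mean FPKM of at least 1 in the higher group. Further named genes are among the up to 4 members of each list with the smallest p, and GAPDH, ACTB, ANG, DICER1, AGO2 and ELAC2. Any other gene named was chosen after its values were seen, including the genes that overlap a named gene. Where rows share a symbol, the one with the highest mean stands for it. Shares of counts were compared by 2-sided exact permutation tests, which cannot give a p under 0.1 with 3 against 3.

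Alternatives fixed beforehand were RLE and upper-quartile scaling, no filter, a mean FPKM of at least 5, limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with a mean FPKM of at least 1, DESeq2 1.42.0, robust empirical Bayes, the replicate number as a block, each library left out in turn, and rows with the same symbol summed. Alternatives chosen after seeing the data were the counts divided by 4, a GC offset per library, and limma voom with library quality weights. GC content is that of the longest transcript in GENCODE 29, which was available for 96.2% of tested genes. Deviation of a library is its log2 CPM minus the mean of the other 5. A gene counts as found nearly only in a library when it has at least 40 counts there and the other 5 together have at most 10% of that count.

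The procedure was tested on simulated data drawn at the size and dispersion of these libraries, in 10 simulations with 200 changed genes each. Unchanged genes were called in 74 of 157210 cases. Correct calls numbered 26, 138, 325 and 420 for changes of 1.5-, 2-, 4- and 8-fold, of 500 each. The share of false calls among all calls was thus above the threshold of 0.05. A list of 30 genes shifted by 0.3 log2 was called in 10 of 10 simulations, and unchanged lists in 0 of 200. The shifted list was drawn from the more highly expressed genes only, and the unchanged lists from unchanged genes of any level. Correlation between genes was not among the properties matched to these libraries, and the mitochondrial list had an estimated correlation of 0.40. The 10 of 10 and the 0 of 200 therefore do not show how often camera calls shifted or unchanged lists here. With the real libraries, the real split into 3 and 3 called 1 list and the other splits 0 to 9. Groups of 3 were not tested for outlying samples. The level of the overexpressed small RNA was not analysed here.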

Results

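Messenger RNA was sequenced in MDA-MB-231 cells, an established line of triple-negative breast cancer. The 6 libraries fall into 2 groups: 3 from cells overexpressing tsRNA-Gly-5-0006, a small RNA derived from a glycine tRNA, and 3 from control cells. Libraries were made from oligo(dT)-selected RNA, so the level of the small RNA itself was not measured. The deposited expected counts summed to 54371226, 61201888 and 74586916 in control 1, 2 and 3. In overexpression 1, 2 and 3 they summed to 73126731, 58870830 and 72488540. These sums were not taken to be tallies of read pairs. Of the 25706 genes in the table, between 19332 and 20688 had a count above 0 in a library. The labels do not say what the control cells carry, so each difference is between these cells as labelled. Nor do they say whether the replicates were separate cultures; if they were not, every p-value here measures only the spread between these samples.

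The comparison asks which mRNAs differ in level between overexpressing and control cells. The mRNAs of the 13 protein-coding mitochondrial genes were higher as a group in the overexpressing cells. They specify subunits of the respiratory chain and of ATP synthase. Their median log2 fold change was 0.21 (overexpression over control, 1.16-fold). The group passed camera with its preset correlation (adjusted p = 3.09e-09) and not with an estimated correlation (adjusted p = 0.934). In the same libraries, transcripts of the ribosomal RNA loci took 1.01% ± 0.659 of counts in control (0.648% without control 1) and 0.246% ± 0.0540 in overexpressing libraries (SD, n = 3 each; exact permutation p 0.1). Messenger RNAs of cytosolic ribosomal proteins, nuclear-encoded oxidative phosphorylation, NF-kB signalling, apoptosis, the integrated stress response and the tRNA machinery had list medians within 0.1 of 0. Among genes with a mean FPKM of at least 1 in the higher group, 9 of the 10 with the smallest p-values had lower means in the overexpressing cells, among them SLC12A4, CRTC1, TNK2 and EXOC3. None of these 10 passed the test over all genes. Collagen and other fibroblast marker transcripts were high in overexpression 1, and without that library the median of their list was -0.18.

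Of 15951 genes tested with edgeR, 0 had an adjusted p under 0.05: 0 higher, 0 lower and 0 over 2-fold. An unadjusted p under 0.05 was reached by 611 genes, 409 higher and 202 lower, where chance alone gives 797.55. The count at that unadjusted level was 307, 386 and 387 without control 1, 2 or 3, 468 without overexpression 1, and 1120 and 1837 without overexpression 2 or 3. DESeq2 passed 12 genes, 3 higher and 9 lower, and limma on log2 FPKM passed 0. Without overexpression 1, edgeR passed 4 genes (WASH2P, EME2, P2RY11 and ENSG00000280064), and without overexpression 2 it passed 2 (ADORA2A and SPECC1L-ADORA2A). These 6 are named because they passed, after their values were seen. Each overlaps other annotated rows, with counts given below. The smallest adjusted p was 0.423, for ENSG00000280064, and the next was 0.994. The 95% confidence interval of a log2 fold change reached a median of 0.53 to either side. For the 3124 tested genes with a mean FPKM of at least 10 it reached 0.27, which is 1.21-fold. In simulated data of the same size, the edgeR test recovered 5.2% of 1.5-fold, 27.6% of 2-fold, 65% of 4-fold and 84% of 8-fold changes. Groups did not overlap for 8.22% of tested genes, where chance gives 10%.

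SLC12A4, a potassium-chloride cotransporter gene (ENSG00000124067, hg38 chromosome 16, 67943474 to 67969192), had 12.8 ± 0.874 FPKM in control and 8.47 ± 0.132 in overexpressing cells (SD, n = 3 each). Its log2 fold change was -0.63 (SE 0.10, unadjusted p 0.000302 by edgeR). CRTC1, a coactivator of CREB (ENSG00000105662, chromosome 19, 18683678 to 18782333), went from 3.23 ± 0.157 to 2.04 ± 0.0952 FPKM, a log2 of -0.71 (SE 0.11, unadjusted p 0.000325). TNK2, a non-receptor tyrosine kinase gene (ENSG00000061938, chromosome 3, 195863364 to 195911945), had 5.77 ± 0.380 against 3.83 ± 0.0879 FPKM and a log2 of -0.63 (SE 0.10, unadjusted p 0.000351). EXOC3, a subunit of the exocyst (ENSG00000180104, chromosome 5, 443175 to 471936), had 9.62 ± 0.331 against 6.87 ± 0.984 FPKM and a log2 of -0.54 (SE 0.09, unadjusted p 0.000426). TRIP10, an adaptor of CDC42 signalling (ENSG00000125733, chromosome 19, 6737925 to 6751530), had 52.8 ± 1.43 against 39.9 ± 4.32 FPKM and a log2 of -0.45 (SE 0.08, unadjusted p 0.000855). Unadjusted p-values of the remaining genes lay between 0.00133 and 0.00178: ILRUN had a log2 of -0.46 (SE 0.09), SLCO4A1-AS2 -0.78 (SE 0.16), and CARD10, a scaffold of NF-kB signalling, -0.38 (SE 0.08). SLCO4A1-AS2 lies antisense to SLCO4A1, which had 1805 to 2443 counts against its 297 to 518. The counting strand is not stated, so the value is not tied to the antisense RNA. For PDCD6, log2 -0.91 (SE 0.18), and SLX1A-SULT1A3, log2 2.41 (SE 0.50), other annotated genes overlap on the same strand, some with counts that go the other way. PDCD6 had 1493, 1644 and 2907 counts in control and 1376, 1027 and 1090 in overexpression libraries, where the overlapping ENSG00000286001 had 1795, 1978 and 71, then 4643, 3669 and 4287. SLX1A-SULT1A3 had 92, 38 and 122, then 279, 501 and 666, where SULT1A3 had 438, 477 and 557, then 555, 212 and 169. Same-strand overlaps with few counts are also annotated for SLC12A4 (LCAT, 90 to 181 counts) and TNK2 (ENSG00000289747, 1 to 4 counts). All 10 had an adjusted p of 0.994, and in all 10 every library of one group lay above every library of the other. Choosing genes by the smallest p favours such a separation, which was found for 8.22% of all tested genes. With DESeq2, 7 of the 10 passed at adjusted p-values from 0.000740 to 0.0414: SLC12A4, CRTC1, TNK2, EXOC3, PDCD6, SLCO4A1-AS2 and SLX1A-SULT1A3.

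The mRNAs of all 13 protein-coding mitochondrial genes had a positive log2 fold change, 12 of 13 with upper-quartile scaling. In 10 of them the groups did not overlap, where chance gives 10% of genes. That rate is for 1 gene. These 13 moved together (estimated correlation 0.40), so they are not independent observations. On the same strand, MT-ATP8 (8366 to 8572) overlaps MT-ATP6 (8527 to 9207), and MT-ND4L (10470 to 10766) overlaps MT-ND4 (10760 to 12137). Overlapping genes can share reads, and each of those named is among the 10. MT-ND2, a subunit of complex I (ENSG00000198763, mitochondrial genome, 4470 to 5511), had 334 ± 7.36 FPKM in control and 431 ± 31.4 in overexpressing cells (SD, n = 3 each). Its log2 fold change was 0.32 (SE 0.08, unadjusted p 0.00558), and that of MT-ATP8, a subunit of ATP synthase, was 0.26 (SE 0.09, unadjusted p 0.0168), or 0.08 (SE 0.12) with a GC offset per library. Relative to the control mean, the median of the 13 was 0.04, -0.04 and 0.04 log2 in control 1, 2 and 3 and 0.33, 0.30 and 0.17 in overexpression 1, 2 and 3. The list passed camera with its preset correlation (adjusted p = 3.09e-09 over 34 lists). With an estimated correlation, which was 0.40, the call was lost (adjusted p = 0.934), and fry gave an adjusted p of 0.359. Adjusted over the list alone, 0 of 13 genes passed, with a smallest p of 0.0725, and over all genes 0 passed. These mRNAs made up 1.08% ± 0.0399 of counts in control and 1.27% ± 0.0633 in overexpressing libraries (SD, n = 3 each; 2-sided exact permutation p 0.1, the smallest that 3 against 3 allows). Mitochondrial ribosomal RNA made up 0.822% and 0.925% (exact permutation p 0.4). In the same libraries, transcripts of the nuclear ribosomal RNA loci took between 0.468% and 1.75% of counts in control and between 0.187% and 0.291% in overexpressing libraries. They are annotated antisense to 18S sequences, and the counting strand is not stated. In addition, 4 RNAs without a poly(A) tail had a median log2 of -0.82, each with an adjusted p of at least 0.994 with edgeR.

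**Figure D1:**
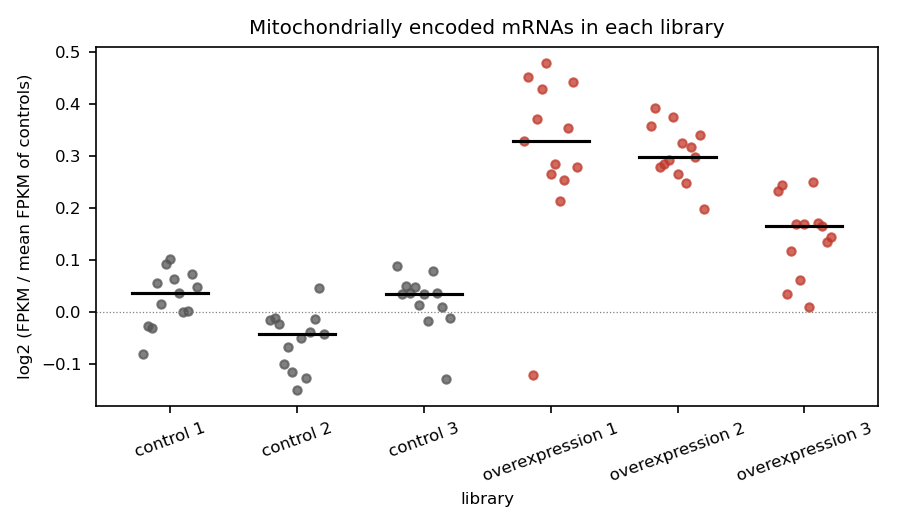
Each point is 1 of the 13 protein-coding mitochondrial genes in 1 library, as the log2 of its FPKM over the mean FPKM of the 3 controls. A bar marks the median of each library. Medians lie between -0.04 and 0.04 in the controls and between 0.17 and 0.33 in the overexpression libraries.

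Other lists on energy and lipid metabolism had no member past the test. Of 23 glycolysis genes, 18 were negative (median log2 -0.07, camera adjusted p = 0.0780, or 0.0404 with the replicate number as a block and 0.0195 with library weights). With an estimated correlation these calls were lost (adjusted p = 0.907 with the block and 0.921 with weights). The list includes PFKM, a phosphofructokinase gene, at -0.19 (SE 0.12), or -0.10 without overexpression 1. Nuclear-encoded oxidative phosphorylation had 31 of 64 positive, and SDHD, a subunit of succinate dehydrogenase, stood at 1.45 (SE 0.69), or 0.01 without overexpression 1. Hypoxia targets had 20 of 30 positive, a median of 0.12 that was -0.01 without overexpression 1. For cholesterol synthesis 10 of 25, and for fatty acid synthesis and storage 14 of 26, were positive.

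Of the 14 fibroblast markers 7 could be tested, and 6 of these were positive, with a median of 2.57 that was -0.18 without overexpression 1. COL1A1 and COL1A2, the chains of type I collagen, had log2 values of 3.04 (SE 1.39) and 2.78 (SE 1.27), and of -0.78 and -0.62 without that library. The list had a camera adjusted p of 0.0780. Counts of this list summed to 118 CPM in overexpression 1 and to between 10.2 and 15.2 CPM in each of the other 5 libraries. The markers of other cells gave 9 of 13 positive for basal or myoepithelial cells, 6 of 12 for luminal or other epithelial lines, and 4 of 9 for leukocytes and endothelium. KRT14, a basal keratin, was at 3.13 (SE 1.05), or 1.16 without overexpression 1. CD68, a lysosomal glycoprotein used as a macrophage marker, had 17.1 ± 1.84 FPKM in control and 12.9 ± 1.89 in overexpressing cells (SD, n = 3 each), a log2 of -0.46 (SE 0.11). It was the single gene of any list that passed when adjusted over the list alone (adjusted p 0.0385 with edgeR), and it did not pass over all genes. That adjustment was made separately in each of 34 lists, so 1 such gene can arise by chance.

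In the lists on the mesenchymal state and the matrix, single genes followed overexpression 1. Of 40 mesenchymal and EMT genes 25 were positive, the median being 0.06, or -0.07 without overexpression 1. SPARC, a matrix glycoprotein, had a log2 of 4.77 (SE 1.78), and MMP2, a gelatinase, of 4.29 (SE 1.64). Without overexpression 1 these were 0.14 and -0.22. Matrix proteases and inhibitors had 15 of 29 positive, 10 with upper-quartile scaling, and epithelial junction genes 16 of 30. Their medians were 0.002 and 0.02, and -0.03 and 0.03 without overexpression 1.

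**Figure D2:**
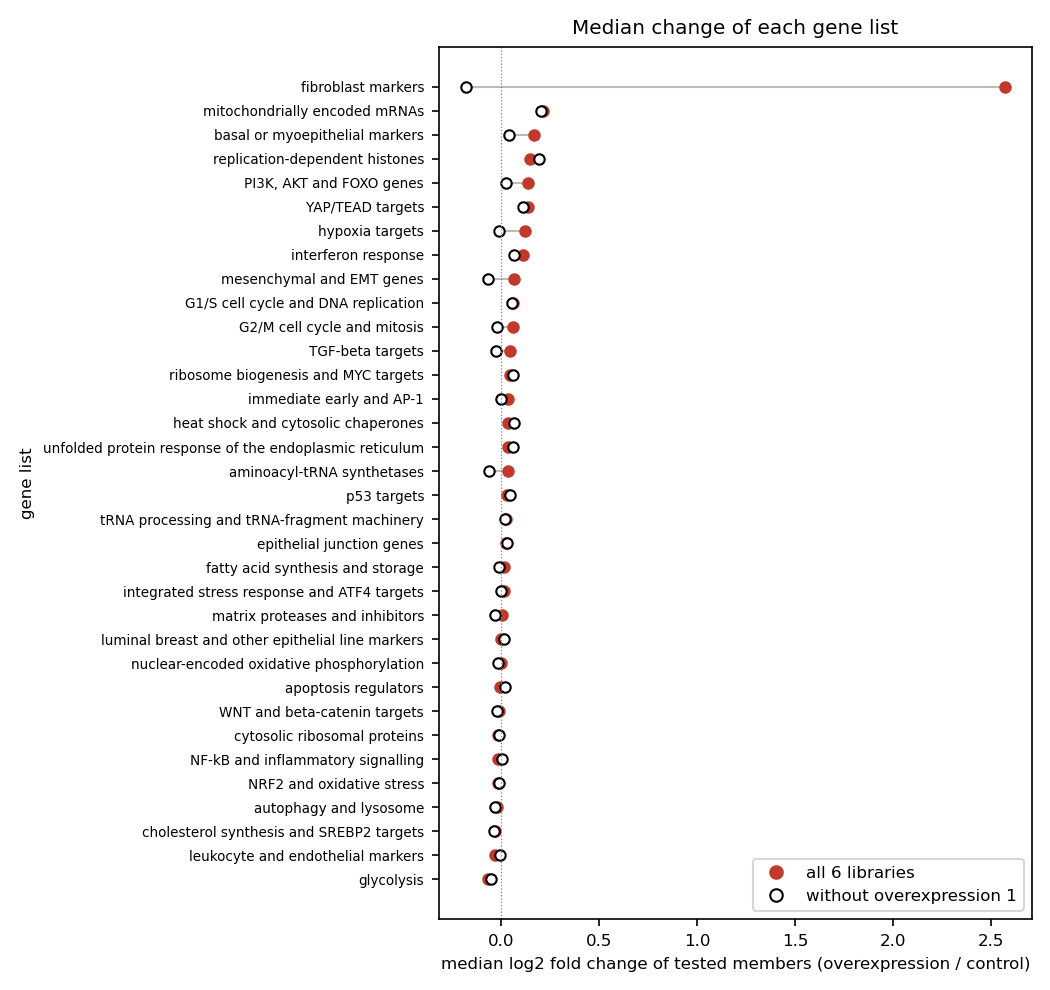
Each row is 1 of the 34 gene lists, and the horizontal axis is the median log2 fold change of its tested members, overexpression over control. Filled points use all 6 libraries and open points leave out overexpression 1, which takes the fibroblast median from 2.57 to -0.18 and the mitochondrial one from 0.21 to 0.20.

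Immune lists had no member past the test over all genes. Of 44 interferon response genes 33 were positive, 28 with upper-quartile scaling (median 0.11, or 0.06 without overexpression 1; camera adjusted p = 0.0780). MX2, an interferon-induced GTPase, had a log2 of 0.91 (SE 0.23) at 0.208 ± 0.0436 against 0.407 ± 0.103 FPKM (SD, n = 3 each). NF-kB and inflammatory signalling had 12 of 26 positive, 8 with upper-quartile scaling. In that list the chemokines CCL2 and CXCL8 had log2 values of 2.63 (SE 0.97) and 0.58 (SE 0.25), and of 0.46 and 0.22 without overexpression 1. CXCL8 was at 0.12 (SE 0.09) with the GC offset. Immediate early and AP-1 genes had 17 of 30 positive, with EGR1 at 1.32 (SE 0.38), or 0.87 without that library.

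In the cell cycle lists, none of which passed, positive values were found for 31 of 48 genes of G1/S and DNA replication, 34 of 56 of G2/M and mitosis, and 11 of 18 replication-dependent histones. PRIM1, the catalytic subunit of DNA primase, had 0.480 ± 0.0952 against 0.839 ± 0.0701 FPKM (SD, n = 3 each) and a log2 of 0.74 (SE 0.21). MAD2L1, of the spindle checkpoint, stood at 1.42 (SE 0.61), or 0.22 without overexpression 1. Of 29 p53 targets 15 were positive, with RRM2B, a ribonucleotide reductase subunit, at 1.22 (SE 0.36), or 0.72 without that library. Apoptosis regulators had 13 of 29 positive, with PMAIP1, a pro-apoptotic BH3-only gene, at 0.63 (SE 0.22), or 0.39 without overexpression 1 and 0.34 with the GC offset.

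Signalling lists were not called with all 6 libraries in the edgeR fit. YAP/TEAD targets had 20 of 23 positive (median 0.14, camera adjusted p = 0.146); the list passed without overexpression 3 (adjusted p = 0.00502) and with library weights (adjusted p = 0.00586), though not with an estimated correlation (adjusted p = 0.779 and 0.921). PI3K, AKT and FOXO genes had 22 of 30 positive, with a median of 0.14, or 0.02 without overexpression 1, and passed without overexpression 3 (adjusted p = 0.0377, or 0.779 with an estimated correlation). TGF-beta targets had 12 of 19 positive, the median being 0.05, or -0.03 without overexpression 1, and WNT and beta-catenin targets had 6 of 13. SMAD6, an inhibitor of TGF-beta family signalling, had 1.15 ± 0.110 FPKM in control and 0.778 ± 0.0882 in overexpressing cells (SD, n = 3 each), a log2 of -0.62 (SE 0.14). Autophagy and lysosome genes had 18 of 39 positive, with TFEB, a transcription factor of lysosomal biogenesis, at -0.38 (SE 0.11).

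Stress and translation lists had medians within 0.1 of 0. Positive log2 values were found for 15 of 30 genes of the integrated stress response, 21 of 31 of the unfolded protein response and 17 of 25 heat shock genes and chaperones. For NRF2 and oxidative stress they were 10 of 25. ATF4, the transcription factor of the integrated stress response, had a log2 of -0.19 (SE 0.10). Cytosolic ribosomal proteins had 33 of 77 positive, 20 with upper-quartile scaling, and made up 10.3% ± 0.629 of counts in control and 10.2% ± 0.873 in overexpressing libraries (SD, n = 3 each; exact permutation p 0.9). Ribosome biogenesis and MYC targets had 22 of 36 positive.

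Genes that process or charge tRNA are of interest because the overexpressed RNA is a tRNA fragment. Of 45 genes of tRNA processing and tRNA-fragment machinery 26 were positive, 22 with upper-quartile scaling, and of 23 aminoacyl-tRNA synthetase genes 13 were positive, 10 with that scaling. SSB, encoding the La protein that binds nascent tRNA, had a log2 of 1.02 (SE 0.46), or 0.19 without overexpression 1, and VARS1, the valyl-tRNA synthetase, of 0.14 (SE 0.09). ANG, a ribonuclease that cleaves tRNA, had a log2 of 0.02 (SE 0.18), which was -0.02 with upper-quartile scaling and -0.08 without control 1. DICER1 had 0.0870 ± 0.0291 FPKM in control and 0.227 ± 0.274 in overexpressing cells (SD, n = 3 each). Its log2 was positive with all 6 libraries and -0.35 (SE 0.31) without overexpression 1. For AGO2 the value was 0.16 (SE 0.17), or 0.01 without overexpression 1. ELAC2, which trims the trailing end of tRNA precursors, stood at -0.08 (SE 0.10), and at 0.00 without overexpression 1. The reference genes GAPDH and ACTB had log2 values of -0.12 (SE 0.13) and -0.00 (SE 0.14); the sign of ACTB changed in 9 of the alternatives, though with neither other scaling of counts.

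Across the 34 lists, 1 passed camera with the preset correlation and 0 passed with an estimated correlation or with fry; the 33 not called had camera adjusted p-values from 0.0780 to 0.987. The number called was 2 without overexpression 2 and 8 without overexpression 3. In 26 lists the median lay within 0.1 of 0, and in 8 it was above 0.1, or in 3 without overexpression 1. Leaving out that library changed the sign of the median in 12 lists: fibroblast and luminal markers, NF-kB, immediate early genes, G2/M, apoptosis, aminoacyl-tRNA synthetases, hypoxia, fatty acid synthesis, mesenchymal genes, matrix proteases and TGF-beta. In 12 lists the median, the mean and camera's direction differed in sign: NF-kB, apoptosis, integrated stress response, NRF2, aminoacyl-tRNA synthetases, ribosomal proteins, nuclear-encoded oxidative phosphorylation, cholesterol synthesis, matrix proteases, TGF-beta, WNT, and autophagy and lysosome. In 9 lists, all with a median within 0.1 of 0, the sign of the median changed with the scaling: immediate early genes, p53 targets, integrated stress response, heat shock, aminoacyl-tRNA synthetases, tRNA processing, fatty acid synthesis, epithelial junctions and matrix proteases.

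Overexpression 1 stood apart from the other libraries. Its mean Pearson correlation with the others, on log2 CPM, was 0.957, against 0.970 to 0.973 for each of the other 5. Genes of the lowest of 5 classes of transcript GC content (26.5% to 41.6%) had a median log2 deviation of 0.51 from the other libraries, and those of the highest class (58.7% to 83.9%) -0.10. In this library 101 genes were found nearly only there, against 1 to 7 in each of the others.

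**Figure D3:**
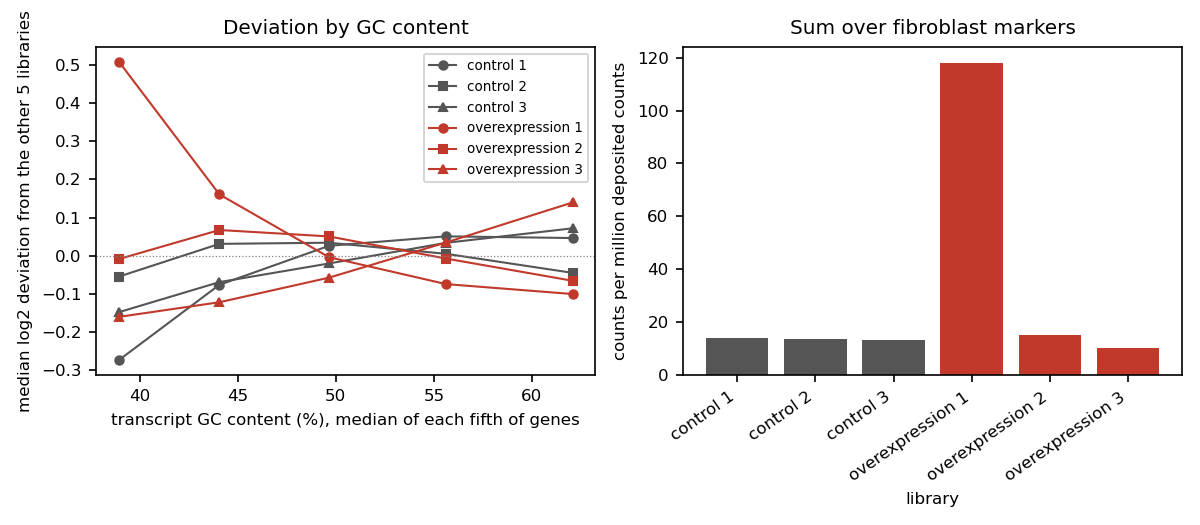
The left plot gives, for each library, the median log2 deviation from the other 5 libraries in each of 5 equal classes of genes by transcript GC content in percent; overexpression 1 reaches 0.51 in the lowest class. The right plot gives the summed counts of the fibroblast markers in CPM of the deposited counts, which are 118 in overexpression 1 and between 10.2 and 15.2 elsewhere.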

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

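Of 19 alternative settings, 16 were fixed before the data were examined; the counts divided by 4, the GC offset per library and the library weights were chosen after seeing the data. The 0 changed genes, with 0 higher, 0 lower and 0 over 2-fold, stood under every alternative but 3. DESeq2 gave 12 changed genes, 3 higher, 9 lower and 6 over 2-fold, and its lists were not tested; the cause was not tested. Leaving out 1 library at a time gave 0 to 4 changed genes, 0 to 1 higher, 0 to 3 lower and 0 to 4 over 2-fold. Of these, the 4 came without overexpression 1 and another 2 (1 higher, 1 lower, 2 over 2-fold) without overexpression 2. The 1 changed list became 2 with no filter, where more fibroblast markers are tested, 2 with the replicate number as a block, 2 with the GC offset and 5 with library weights. It became 0 with an estimated correlation and 0 with fry, and ranged from 1 to 8 without 1 library, at 2 without overexpression 2 and 8 without overexpression 3. Beside the mitochondrial list, the fibroblast list passed with no filter, with the GC offset and without overexpression 2, and glycolysis with the block (adjusted p 0.0404). With library weights glycolysis (0.0195), YAP/TEAD targets (0.00586), ribosomal proteins and nuclear-encoded oxidative phosphorylation passed. Without overexpression 3 the last 2, YAP/TEAD targets (0.00502), PI3K, AKT and FOXO genes (0.0377), and the mesenchymal, basal and fibroblast lists passed; the cause was not tested. None of these further list calls held with an estimated correlation (adjusted p 0.779 to 0.967). The mitochondrial list passed under every alternative of camera with the preset correlation, at medians of 0.16 to 0.26. The block was run because replicate numbers recur in both groups, but they do not pair the samples: residual correlations between samples of the same number were -0.03, 0.04 and 0.07. With it, 0 genes passed and 438 had an unadjusted p under 0.05. Over the alternatives that rescale counts or change the filter, the median log2 of all tested genes lay between -0.01 and 0.04.

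Of 691 values of 39 named genes under alternatives, 17 had the other sign, in 7 genes. ACTB, at -0.00 as reported, was 0.0060 with no filter, 0.036 at a mean FPKM of at least 5, 0.043 and 0.043 with limma on FPKM, 9.24e-05 with counts divided by 4 and 0.037 with the GC offset, and -0.086 to 0.086 without 1 library. ANG was -0.015 with upper-quartile scaling and -0.076 to 0.16 without 1 library. Without 1 library, the fibroblast median ranged from -0.18 to 3.0, COL1A1 from -0.78 to 3.60, COL1A2 from -0.62 to 3.35, MMP2 from -0.22 to 4.88 and DICER1 from -0.35 to 1.75. In these 5 the negative value is the one without overexpression 1. ELAC2 ranged from -0.14 to 0.00026. SPARC, MMP2 and DICER1 had low means in control, of 0.0313, 0.0529 and 0.0870 FPKM. Outside overexpression 1, SPARC had 4 to 16 counts in each library and MMP2 12 to 26, so few counts underlie these values. Whether depth limits the values of SPARC, MMP2 and DICER1 was not tested.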

Other observations

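The tests of the overexpression itself, of histone genes, of foreign reads in a fixed share and of fibroblast markers against genes of like GC content were chosen after the results they concern were seen, as were the ribosomal RNA values without control 1, the split count for unadjusted p-values and the single genes named in this part.

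Overexpression 1 held transcripts that the other 5 libraries nearly lacked. COL3A1, a fibrillar collagen, had 962 counts there and 0 in the other 5 together, and VCAN, a matrix proteoglycan, 1719 and 0. GJA1, a gap junction connexin, had 2278 against 218, MMP2 1255 against 87, and SPARC 984 against 53. These genes are a selection, and genes of other kinds had counts as high. ENSG00000289256 had 1318 against 19, INO80D 1222 against 106, and RGS17 1080 against 67. Of the fibroblast markers, DCN had 52 counts and FAP 51 in this library and 0 in the others. In all, 101 genes were nearly confined to overexpression 1, of which 64 had 0 counts elsewhere, against 1 to 7 genes for each other library. Of the 12 fibroblast markers in the table, 2 also stand in another list and 5 have counts in all 5 other libraries.

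At some loci, counts of overlapping genes on the same strand differed between libraries in opposite directions. ADORA2A, the adenosine A2a receptor gene, had 2097, 2478 and 2907 counts in control 1, 2 and 3, and 223, 2742 and 222 in overexpression 1, 2 and 3. The readthrough gene SPECC1L-ADORA2A had 0 in each control, and 2445, 0 and 2498. P2RY11, a nucleotide receptor gene, had 561, 581 and 743 counts in control and 371, 133 and 114 in overexpression libraries. PPAN-P2RY11 had 595, 1359 and 2044, then 2380, 2462 and 2282. The row that passed as WASH2P had 143, 184 and 342, then 189, 0 and 0. Another row of that symbol on the same strand had 544, 694 and 486, then 859, 1029 and 1061. EME2 had 129, 210 and 239, then 363, 1071 and 2025. It overlaps MRPS34 (10976 to 16562 counts) and SPSB3 (5106 to 8835) on the other strand, and the counting strand is not stated.

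ENSG00000280064, the gene with the smallest p, had 85, 61 and 93 counts in control and 0 in each overexpression library. It overlaps RAB11FIP1 on the other strand, which had 410, 450 and 423 counts in control and 1285, 589 and 510 in overexpression libraries, and the counting strand is not stated.

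A change shared by the overexpressing cells was not seen to explain why overexpression 1 stands apart. Overexpression 1 less control 1 and overexpression 2 and 3 less control 2 and 3 had a correlation across genes of 0.028. Noise and the GC trends of control 1 (0.29) and overexpression 3 (0.26) could hide a small shared change. The value therefore argues only against a large one. A stronger effect in overexpression 1 alone was not tested. GC-dependent recovery may account for part of how that library stands apart. Its deviation had a Spearman correlation of -0.41 with GC content across genes, against -0.07 to 0.29 in the other 5. GC content does not account for the fibroblast markers, which exceeded genes of like GC content by a median of 3.87 log2. RNA or cells of a fibroblast-like type are a candidate source of these. Their median deviation of 3.79 is the pattern itself and no separate support. PDGFRB (0.30) and FBLN1 (-0.04), which the other libraries also express, were not raised alike. The other 3 marker lists had median deviations of at most 0.12. This does not exclude other cell types, because those lists hold genes expressed in every library, such as KRT19 and CD14 (means of 2083 and 14.7 FPKM in control). Foreign reads in a fixed small share stay open: level and deviation had a correlation of -0.030 in the lowest GC class, and the bound set for excluding them was wrong, because it took levels in the foreign RNA to be unrelated to levels here. These correlations are across genes, which are not independent replicates, and the labels state no sort or gate.

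Transcripts of the ribosomal RNA loci were lower in the overexpression libraries. They are 4 transcripts on chromosome 21 annotated antisense to 18S sequences, 3 inside 18S genes and 1 inside the pseudogene RNA18SP5, and they took 1.01% ± 0.659 of counts in control and 0.246% ± 0.0540 in overexpressing libraries (SD, n = 3 each; exact permutation p 0.1), with log2 values of -2.08 to -1.99 and an adjusted p of 0.994 with edgeR. Control 1 carries much of this: the controls had 1.75%, 0.828% and 0.468%, and without control 1 their mean was 0.648% and the log2 values were -1.43 to -1.35. If their reads come from ribosomal RNA, which the unstated counting strand leaves open, carry-over of RNA without a poly(A) tail is a candidate explanation. Other such RNAs were chosen after RN7SL2 had been seen, and RN7SL2 was left out. VTRNA and SCARNA genes were planned but were not among those tested. RN7SL1 (-0.60, SE 0.27), RN7SK (-1.10, SE 0.31), RPPH1 (-0.29, SE 0.24) and RMRP (-1.05, SE 0.29) were all negative, with a median of -0.82. Each had an adjusted p of at least 0.994 with edgeR. Replication-dependent histone genes, whose main mRNAs also lack the tail, did not go with these RNAs (median 0.144, 11 of 18 positive, -0.52 to 0.51). Carry-over of all such RNA alike is therefore not shown. Polyadenylated histone transcripts, which cannot be told apart here, keep it open. An effect of the overexpression stays open too, since selection efficiency was not measured.

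AT-rich transcripts had low values in every library. The Spearman correlation of GC content with log2 FPKM across genes was 0.28 to 0.38 in each, and the median FPKM rose from 0.431 in the lowest GC class to 4.60 in the highest. GC-dependent recovery in library preparation may contribute: over 22 subunits of the CCT chaperonin and the 20S proteasome core, which assemble in fixed proportions, the Spearman correlation was 0.80 and Pearson's r 0.774 (permutation p 3e-05 for the former, across genes that are not independent). Within the 14 proteasome subunits the Spearman correlation was 0.855, and within the 8 CCT subunits 0.286. PSMB5 had 319 FPKM and PSMA4 1.08, and no biological explanation was tested.

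The 6 libraries form 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 0 changed genes and the highest other 1, likewise 0 and 1 for over 2-fold. That 1 gene, of the split with control 1, control 3 and overexpression 3 together, is the only call in any split, and it counts for higher as for lower because a split and its mirror are one. With a real count of 0, all 10 of 10 splits are as large by construction, which says nothing about chance. For changed lists the real split gave 1 and the highest other 9, and 9 of 10 splits were as large. For genes at an unadjusted p under 0.05 the real split gave 611 and the highest other 1775, and 5 of 10 were as large. The split with 1775 such genes and 9 lists sets control 1, control 3 and overexpression 3 against the rest, which points to a structure of the samples other than the groups; these libraries have the 3 highest correlations of deviation with GC content (0.24 to 0.29).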
